A study of Arabidopsis thaliana with 36 samples.

How the data were processed

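Gene expression was measured by RNA sequencing in young plants of Arabidopsis thaliana. Per the labels' protocols, seedlings were moved at 6 days to liquid medium, with 25 mM sucrose for the flg22 experiment and without sucrose for the 2DG experiment, and treated 1 day later with 1 µM flg22 or 1 mM 2DG, at 22 °C with 16 h of light. Strand-specific 3′ digital gene expression libraries (BrAD-seq) were made from 500 ng of RNA, per the labels' protocols. Reads were processed with fastp 0.19.7, aligned with STAR 2.6.1b to TAIR10 and counted with featureCounts 1.6.0, per the submitters' processing notes. The values deposited by the authors are counts of reads per gene, featureCounts being named in the processing notes and both tables holding whole numbers. One table holds the 10 h libraries and the sucrose and 2DG libraries, the other the 2 h and 24 h libraries, so the 10 h time point is confounded with the table.

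Both tables list the same 32833 loci. Of these, 32548 were matched by locus tag to the RefSeq annotation TAIR10.1, which was used for names only, and 10804 had a symbol. That build differs in name from the one the submitters used, and no coordinates are given. Whether reads were counted by strand is not stated, so values of genes that overlap an antisense partner are uncertain, as are those of near-identical families such as LHCB, RBCS and the pair CYP71A12 and CYP71A13, whose reads the counting could split. Total counts per library ranged from 8.06 to 20.1 M, and the floor of 3 counts used below covers counting error only.

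Groups were taken from the sample titles. For 6 libraries the title and the treatment label name 2DG_1mM and Suc_25mM the other way round, and the groups from the treatment label were run as an alternative. The same-numbered libraries of a time were treated as coming from 1 of the 3 trials, since the design text names 3 independent trials, though which number belongs to which trial is not stated. As a check of this pairing, deviations from the group means were correlated across genes between libraries. At the same time, same-numbered libraries gave a median of 0.190 (0.021 to 0.530) in the 2 h and 24 h data, 0.020 (-0.075 to 0.072) in the 10 h data and 0.033 (-0.018 to 0.242) in the sucrose and 2DG data. In the last, the 3 same-numbered pairs of Suc_0mM and Suc_25mM libraries gave 0.230, 0.242 and 0.123, and the 6 pairs with a 2DG_1mM library -0.018 to 0.042. Libraries with different numbers gave -0.076, -0.001 and -0.019. Genes are not independent replicates, and these correlations carry no test. No pair of libraries of a group held identical counts.

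In R 4.3.3, edgeR 4.0.16 was used with TMM scaling, its default filter on low counts (filterByExpr) and a quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Separate fits held the 18 libraries of 2 h and 24 h, the 9 of 10 h and the 9 of the sucrose and 2DG experiment. They gave 12 comparisons of groups and 2 interactions of genotype and time. The fits had no term for the trial, so the reported counts and p-values leave the pairing out. The trial as a block was run as an alternative. The fitted p-values rest on 3 trials. Log2 fold changes are given with their standard errors, and levels as CPM. For a gene with no count in all 3 libraries of a group, the fold is a lower bound against a floor of 3 counts over the group.

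The comparisons, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule names FLS2, STP1, STP4 and STP13. It adds the 5 genes with the largest rise and the 5 with the largest fall past the threshold, with a symbol, a mean log2 CPM of at least 3 and the same direction in all 3 same-numbered pairs, and up to 3 past the threshold from each list. For the interactions the condition on pairs was not applied. Only some of the genes that the rule names are printed, others being left out for length, among them some with few counts. The 17 lists cover pattern-triggered immunity, salicylic acid and systemic acquired resistance, camalexin and indole glucosinolate, jasmonate, ethylene, ER protein folding and secretion, sugar starvation, sugar-induced metabolism, anthocyanin, photosynthesis, sugar transport and phosphorylation, abscisic acid and clade A PP2C, calcium-dependent protein kinase, cell cycle, root tissue markers, guard cell markers and heat shock. Together with FLS2, STP1, STP4 and STP13, the lists held 368 written members, of which 13 were dropped or were duplicates. A symbol not paired with its written locus in the reference took the only locus that bore the symbol. It was dropped where no single locus did. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison.

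The response of stp1/4/13 was set against that of Col by the median ratio of their log2 differences from fls2, over genes called higher in Col, with 20 simulated draws of stp1/4/13 libraries equal to Col. Comparisons that share control libraries were set against 20 simulated draws of unchanged groups. Other splits of the 6 libraries of each comparison were counted, 10 in all with the real one. For each interaction 30 groupings were counted, also with the real one, with times shuffled within genotype.

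Alternatives were RLE scaling, no filter on low counts, a strict filter (5 CPM in 3 libraries), the trial as a block, DESeq2 1.42.0, only the compared groups in the fit, each library left out in turn, groups from the treatment label, and, for the ratio, genes called at another time. A block within each time, the removal of the 3 libraries numbered 3 at 24 h, and the removal of each library from the ratio were added after seeing the data.

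The steps were tested on simulated counts with the real genes, means and library sizes, in which 200 genes were changed, 100 at each fold size. The other members of the photosynthesis list were also raised 2-fold. Recovery was counted over the 200 genes, and calls outside both sets were counted as false. For stp1/4/13 against Col, 29% of genes changed 2-fold and 84% of genes changed 4-fold were recovered at 2 h among 21463 genes, with 7.52% of calls false. At 10 h these were 48%, 91% and 6.08% among 19561 genes, and at 24 h 35%, 83% and 5.07% among 21463 genes. For Suc_25mM against Suc_0mM they were 3%, 50% and 1.61% among 19727 genes. The adjusted threshold depends on how many genes change, so recovery in the real comparisons can differ.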

Results

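Arabidopsis thaliana seedlings were profiled by strand-specific 3′ digital gene expression after treatment with flg22, a peptide of bacterial flagellin perceived by the receptor kinase FLS2, or with 2-deoxy-d-glucose (2DG), a glucose analogue. The 36 libraries fell into 12 groups of 3, 1 library from each of 3 independent experimental trials. The wild type Col, the triple sugar transporter mutant stp1/4/13 and the receptor mutant fls2 were sampled 2, 10 and 24 h after 1 µM flg22. The other groups were Col seedlings sampled at 24 h and titled Suc_0mM, Suc_25mM and 2DG_1mM. Total counts ranged from 17.2 to 19.6 M per library at 2 h, from 9.46 to 11.3 M at 10 h, from 16.0 to 20.1 M at 24 h and from 8.06 to 12.9 M in the sucrose and 2DG groups. No mock-treated group is among the labels, so fls2 served as the background for flg22, and any effect of the fls2 genotype itself is included in those differences. Differences of stp1/4/13 from fls2 or Col likewise include any effect of the stp1/4/13 genotype without flg22. Fold changes below are log2 values ± standard error with n = 3 libraries per group, and levels are CPM (counts scaled to a common library total), mean ± SD.

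FLS2 counts were low in fls2, and STP1, STP4 and STP13 were lower in stp1/4/13 than in Col. FLS2 (AT5G46330) had 0.142 ± 0.0526 CPM in fls2 at 2 h, 0.165 ± 0.0511 at 10 h and 0.141 ± 0.0311 at 24 h, against 47.1 ± 11.3, 22.3 ± 2.78 and 21.8 ± 9.62 in Col. STP13 (AT5G26340), a hexose-proton symporter, had 7.85 ± 0.266 CPM in stp1/4/13 and 181 ± 5.88 in Col at 2 h. STP1 (AT1G11260), another hexose transporter, had 9.44 ± 4.16 CPM in stp1/4/13 and 299 ± 79.3 in Col at 10 h. STP4 (AT3G19930) was lowered least, to 55.2 ± 10.4 CPM in stp1/4/13 against 376 ± 48.2 in Col at 2 h. Against fls2, STP1 was lower in stp1/4/13 by -2.85 ± 0.67 log2 units at 2 h, -3.26 ± 0.28 at 10 h and -4.02 ± 0.72 at 24 h. STP4 did not pass against fls2 at 2 h (0.05 ± 0.23, edgeR adjusted p = 0.9) or 24 h (-0.03 ± 0.23, edgeR adjusted p = 0.95) and was higher at 10 h (0.44 ± 0.14, edgeR adjusted p = 0.015, and 0.11 without stp1/4/13 library 3, with 0.0077 to 0.11 over the alternatives). STP13 did not pass at 2 h (0.55 ± 0.30, edgeR adjusted p = 0.19) or 10 h (-0.53 ± 0.24, edgeR adjusted p = 0.067) and was lower at 24 h (-1.68 ± 0.29). At 10 h STP13 passed with DESeq2, with no filter, with the strict filter and without fls2 library 1 (adjusted p from 1.5e-04 to 0.25 over the alternatives). Reads of a mutated gene can persist on a 3′ tag, and where the mutations lie relative to the counted tag is not stated. At 2 h, STP1 stood at 29.1 CPM in stp1/4/13 library 2 and at a mean of 2.96 CPM in libraries 1 and 3.

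**Figure D1:**
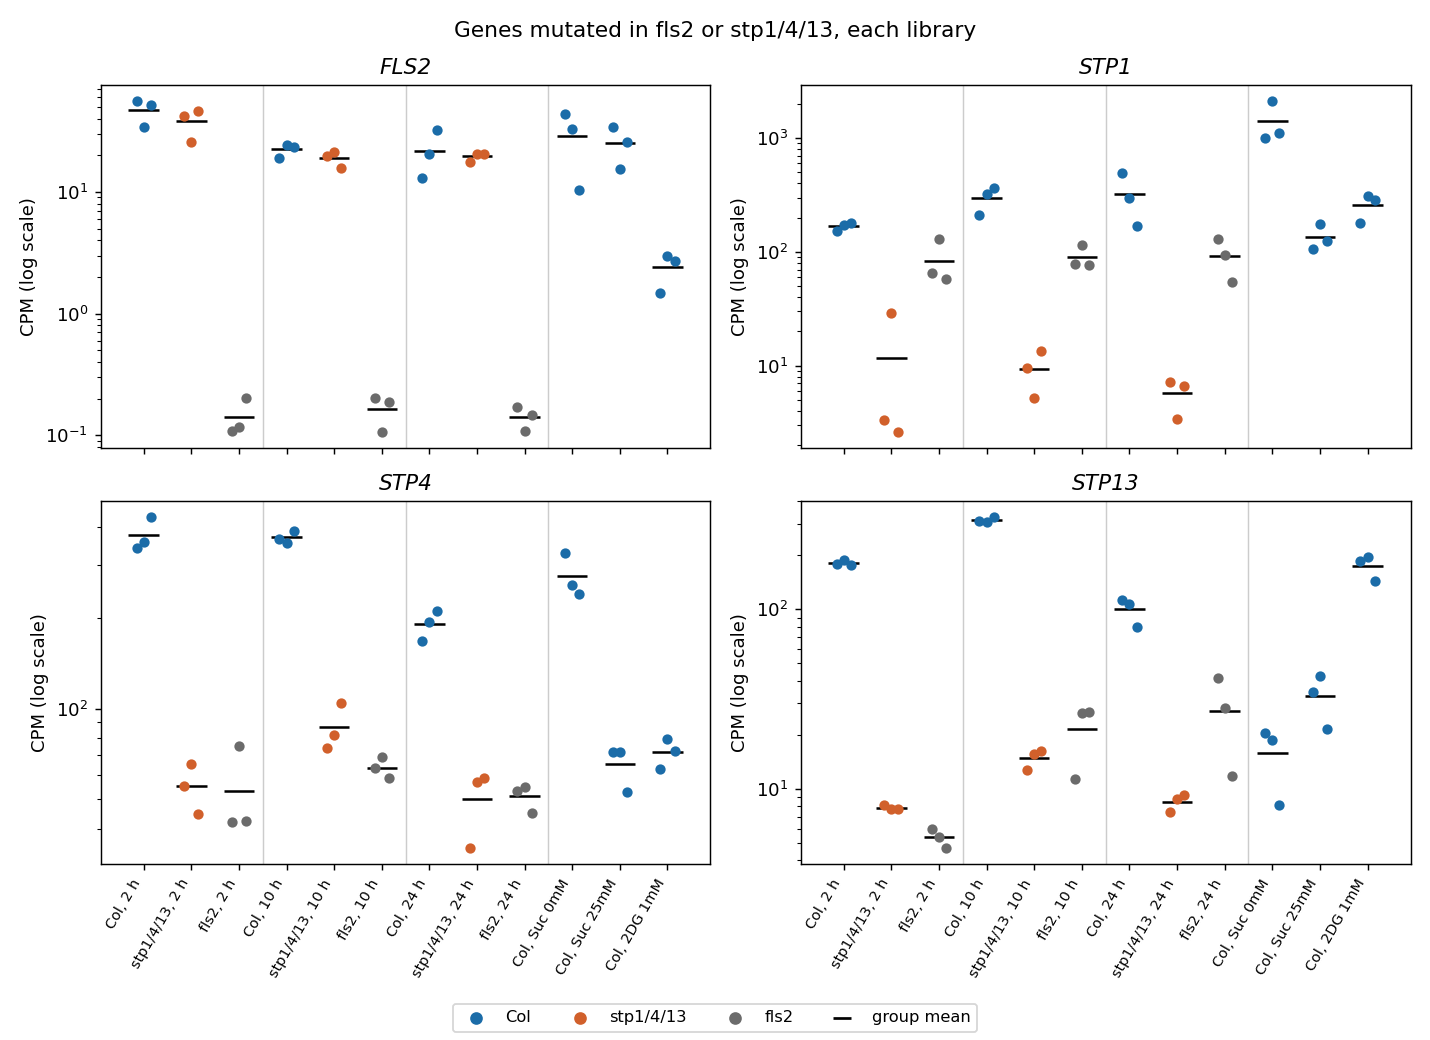
Normalised read counts (CPM, log axis) of FLS2, STP1, STP4 and STP13 in each library (points) of the 12 groups, with the group mean as a black line; CPM were scaled separately within the 2 h and 24 h, the 10 h, and the sucrose and 2DG libraries. STP1 at 29.1 CPM in stp1/4/13 library 2 at 2 h stood apart from its group.

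The response to flg22 was read from Col against fls2, which asks what the peptide changes where its receptor is present. At 2 h, defence genes rose by up to 8.04 ± 0.87 (CYP82C3, a cytochrome P450 related to the indole carbonyl nitrile enzyme CYP82C2). The receptor-like kinase FRK1, a marker of flg22 perception, rose by 7.70 ± 0.56, from 0.794 ± 0.391 to 166 ± 25.1 CPM. The peroxidase PRX52 rose by 7.80 ± 0.47, and PROPEP3, the precursor of a danger peptide, by 7.57 ± 0.54. All 3 sugar transporter genes had higher means in Col: STP13 rose by 5.08 ± 0.33 and STP4 by 2.82 ± 0.25, while STP1 differed by 1.00 ± 0.63 and did not pass (edgeR adjusted p = 0.23, and 0.01 to 0.44 over the alternatives). STP1 passed with only the compared groups in the fit and with the block set within each time, the latter chosen after the data were seen. GASA6 fell by -4.13 ± 0.43 log2 units, the arabinogalactan protein gene AGP17 by -3.86 ± 0.27 and the cell wall enzyme gene XTH6 by -3.67 ± 0.52.

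Of the pattern-triggered immunity list, 29 of 30 members rose at 2 h, and 29 when adjusted over the list alone, WRKY30 among them by 7.41 ± 0.73 (camera adjusted p = 9.7e-21, adjusted p = 0.015 with an estimated correlation). All 21 members of the camalexin and indole glucosinolate list rose, also 21 adjusted over the list alone: the glucosinolate methyltransferase IGMT2 by 6.11 ± 0.47 and CYP71A12, an enzyme of indolic phytoalexins, by 5.45 ± 0.48 (camera adjusted p = 2.2e-19, adjusted p = 0.029 with an estimated correlation). Calcium-dependent protein kinases rose in 9 of 10 cases, 9 adjusted over the list alone, with CPK29 at 1.94 ± 0.20 and CPK32 at 1.66 ± 0.20 (camera adjusted p = 7.6e-06, adjusted p = 0.034 with an estimated correlation). In the salicylic acid list 19 of 30 members rose (19 adjusted over the list alone), led by the regulators NIMIN-1 (5.10 ± 0.56) and CBP60G (4.64 ± 0.37). The list had camera adjusted p = 6e-07 and adjusted p = 0.062 with an estimated correlation. In the jasmonate list 17 of 30 rose (17 adjusted over the list alone), such as LOX4 (3.85 ± 0.50) and TAT3 (3.84 ± 0.66). As a list they had camera adjusted p = 7.6e-06 and adjusted p = 0.31 with an estimated correlation. The ACC synthase genes ACS2 (4.66 ± 0.27) and ACS7 (3.77 ± 0.31) were among 12 of 17 ethylene genes that rose (12 adjusted over the list alone). Together they had camera adjusted p = 2.7e-07 and adjusted p = 0.062 with an estimated correlation.

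In the endoplasmic reticulum (ER) protein folding list 12 of 18 members rose at 2 h (12 adjusted over the list alone), including the chaperone BIP3 (5.70 ± 0.85) and the transcription factor BZIP60 (2.24 ± 0.18). All members together had camera adjusted p = 1e-04 and adjusted p = 0.36 with an estimated correlation. Photosynthesis genes fell in 33 of 34 cases (33 adjusted over the list alone), among them the antenna genes LHCB2.2 (-2.70 ± 0.50) and LHCB1.1 (-2.69 ± 0.46) and the Rubisco small subunit gene RBCS1B (-2.51 ± 0.43). Over the whole list, the members had camera adjusted p = 8.5e-15 and adjusted p = 0.27 with an estimated correlation. Anthocyanin genes fell in 8 of 14 cases (9 adjusted over the list alone), such as the regulator MYB75 (-3.00 ± 0.67), with camera adjusted p = 0.001 and adjusted p = 0.36 with an estimated correlation. The list of sugar-induced metabolism moved both ways, with the cell wall invertase cwINV1 (3.11 ± 0.18) and PAL1 (3.10 ± 0.36) among 3 that rose and the starch gene APL3 (-2.81 ± 0.50) among 5 that fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.87). Sugar transport genes also split, 5 higher and 6 lower of 23 (5 and 6 adjusted over the list alone, camera adjusted p = 0.87), with the polyol transporter PMT5 at 3.30 ± 0.27. In the abscisic acid list, 6 of 18 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.32), the transcription factor ABI5 by 4.28 ± 0.46. Heat shock genes, fixed as a marker of handling, rose in 6 of 11 cases (7 adjusted over the list alone), HSP90.1 by 2.00 ± 0.44. The list had camera adjusted p = 0.0072 and adjusted p = 0.36 with an estimated correlation. In total, edgeR's quasi-likelihood test called 7476 of 21463 genes at a Benjamini-Hochberg adjusted p below 0.05, 4024 higher and 3452 lower in Col.

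At 10 h, the defence genes CYP71A12, CYP82C2, PER4 and PRX52 were higher in Col than in fls2. CYP71A12 stood at 1410 ± 131 CPM in Col and 7.67 ± 1.28 in fls2, a change of 7.51 ± 0.18, and CYP82C2, an enzyme of the indole carbonyl nitrile pathway, rose by 8.39 ± 0.49. The peroxidase genes PER4 and PRX52 rose by 8.15 ± 0.28 and 7.36 ± 0.30. AGP30 had no count in the 3 Col libraries and 24.3 ± 5.38 CPM in fls2, at least 252-fold lower with a floor of 3 counts over the group. The proline-rich protein gene PRP3 changed by -5.80 ± 0.62. The sugar transporter genes STP13 (3.86 ± 0.24), STP4 (2.53 ± 0.15) and STP1 (1.73 ± 0.25) were higher in Col.

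By list at 10 h, 26 of 29 pattern-triggered immunity genes rose (26 adjusted over the list alone), NHL10 by 7.05 ± 0.29 and FRK1 by 6.60 ± 0.19. As a list they had camera adjusted p = 2.2e-13 and adjusted p = 0.1 with an estimated correlation. In the salicylic acid list 26 of 29 rose and 1 fell (26 and 1 adjusted over the list alone), with the biosynthetic enzyme PBS3 at 5.40 ± 0.30 and CBP60G at 5.31 ± 0.17. Together they had camera adjusted p = 9.7e-10 and adjusted p = 0.13 with an estimated correlation. All 21 camalexin and indole glucosinolate genes rose (21 adjusted over the list alone), including the glutathione transferase GSTF6 (4.40 ± 0.29), with camera adjusted p = 1.6e-11 and adjusted p = 0.13 with an estimated correlation. The sugar starvation list rose in 23 of 29 members (23 adjusted over the list alone), such as the branched-chain aminotransferase BCAT-2 (3.87 ± 0.30) and the dark-inducible glucosidase DIN2 (3.18 ± 0.36). All members together had camera adjusted p = 5.9e-08 and adjusted p = 0.1 with an estimated correlation. ER protein folding genes rose in 15 of 18 cases (15 adjusted over the list alone), BIP3 by 5.26 ± 0.26 and BZIP60 by 1.58 ± 0.19. Over the whole list, the members had camera adjusted p = 8.6e-05 and adjusted p = 0.12 with an estimated correlation. Ethylene genes rose in 13 of 17 cases (13 adjusted over the list alone), ACS8 by 5.53 ± 0.37 and ACS2 by 5.22 ± 0.30. The list had camera adjusted p = 2.2e-05 and adjusted p = 0.1 with an estimated correlation. Jasmonate genes split, 11 higher and 5 lower of 29 (11 and 5 adjusted over the list alone, camera adjusted p = 0.15), with the defensin PDF1.2b at 4.00 ± 0.38 and CORI3 at -5.83 ± 0.62.

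Cell cycle genes fell in 8 of 14 cases at 10 h (8 adjusted over the list alone), among them the Aurora kinase AUR2 (-1.77 ± 0.50) and the cyclin CYCA1;1 (-1.37 ± 0.32). As a list they had camera adjusted p = 0.0097 and adjusted p = 0.13 with an estimated correlation. Anthocyanin genes fell in 7 of 9 cases (8 adjusted over the list alone), LDOX by -4.55 ± 0.81 log2 units, with camera adjusted p = 5.9e-04 and adjusted p = 0.13 with an estimated correlation. Photosynthesis genes fell in 17 of 34 cases and rose in 2 (17 and 2 adjusted over the list alone), with RBCS1B at -1.87 ± 0.25 and LHCB1.4 at 2.43 ± 0.15. Together they had camera adjusted p = 0.015 and adjusted p = 0.6 with an estimated correlation. In the list of root tissue markers, 8 of 17 fell and 2 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.13), including the expansin EXPA18 (-5.21 ± 0.72) and the root hair gene LRX1 (-4.50 ± 0.76). These root genes fell in the comparison in which the defence lists rose, and no tissue was separated. In the sugar lists, cwINV1 (3.82 ± 0.17) and PAL1 (3.53 ± 0.20) rose while the starch synthase GBSS1 changed by -4.09 ± 0.27 and the sugar exporter SWEET1 by -2.43 ± 0.23. CPK11 was among 8 of 10 calcium-dependent kinases that rose (8 adjusted over the list alone), with camera adjusted p = 0.0037 and adjusted p = 0.13 with an estimated correlation. RD29A, an abscisic acid and cold marker, changed by -2.88 ± 0.27 and HSP90.1 by 1.34 ± 0.25. edgeR called 10035 of 19561 genes (Benjamini-Hochberg), 4863 higher and 5172 lower in Col.

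At 24 h the defence response was still present in Col. CYP82C2 stood 7.13 ± 0.67 above fls2, PRX52 6.53 ± 0.47, FRK1 5.49 ± 0.52 and PER4 5.19 ± 0.47. The beta-amylase gene BAM5 fell by -5.73 ± 0.79 log2 units, from 212 ± 143 to 3.96 ± 0.80 CPM, and the jasmonate-responsive gene CORI3 by -4.78 ± 0.58. The root genes EXT13 (-5.51 ± 0.41), PRP3 (-3.26 ± 0.35), EXPA18 (-2.51 ± 0.31) and LRX1 (-2.17 ± 0.26) were lower, with AGP30 at 0.118 ± 0.108 CPM against 9.84 ± 4.53. STP4 rose by 1.90 ± 0.24 and STP13 by 1.88 ± 0.29. STP1 differed by 1.79 ± 0.64 and did not pass (edgeR adjusted p = 0.058, 0.034 with the trial as a block, and 0.0075 to 0.23 over the alternatives).

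In 22 of 30 cases pattern-triggered immunity genes rose at 24 h (26 adjusted over the list alone), with camera adjusted p = 1.6e-15 and adjusted p = 0.022 with an estimated correlation. Salicylic acid genes rose in 21 of 30 cases (24 adjusted over the list alone), PBS3 by 4.69 ± 0.39 and NIMIN-1 by 3.80 ± 0.50. All members together had camera adjusted p = 1.2e-14 and adjusted p = 0.021 with an estimated correlation. Camalexin and indole glucosinolate genes rose in 17 of 21 cases (19 adjusted over the list alone), CYP71A12 by 4.64 ± 0.46 and CYP79B2, which makes indole-3-acetaldoxime, by 2.62 ± 0.29. Over the whole list, the members had camera adjusted p = 8.9e-15 and adjusted p = 0.047 with an estimated correlation. The ethylene genes ACS2 (3.61 ± 0.27) and ACS7 (3.35 ± 0.31) were among 9 of 17 that rose (10 adjusted over the list alone). The list had camera adjusted p = 4.3e-06 and adjusted p = 0.13 with an estimated correlation. In the sugar starvation list 11 of 29 rose and 1 fell (12 and 1 adjusted over the list alone), with the pyruvate dikinase PPDK at 1.84 ± 0.18 and DIN4 at 2.14 ± 0.41. As a list they had camera adjusted p = 1e-04 and adjusted p = 0.4 with an estimated correlation. Jasmonate genes split, 3 higher and 4 lower of 30 (4 and 5 adjusted over the list alone, camera adjusted p = 0.51), with the allene oxide cyclases AOC1 (-1.91 ± 0.39) and AOC2 (-1.61 ± 0.39) lower. The invertases cwINV1 (2.14 ± 0.18) and CWINV6 (1.91 ± 0.27) were higher, and GPT2, a plastid glucose-6-phosphate translocator (-2.21 ± 0.39), and SWEET1 (-1.89 ± 0.28) lower. Photosynthesis genes fell in 3 of 34 cases (2 adjusted over the list alone), RBCS1A by -0.98 ± 0.23 log2 units, with camera adjusted p = 0.0011 and adjusted p = 0.68 with an estimated correlation. edgeR called 3984 of 21463 genes, 2355 higher and 1629 lower in Col, and 2090 with only the compared groups in the fit.

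The change of the flg22 response from 2 h to 24 h was tested as an interaction within 1 table. It was negative for WRKY30 (-5.46 ± 0.97), PROPEP3 (-4.17 ± 0.66), IGMT2 (-3.88 ± 0.56) and STP13 (-3.20 ± 0.41). It was positive for PCR1, a cadmium resistance family gene (5.13 ± 0.61), and the defence gene LURP1 (4.06 ± 0.78). The interaction was negative for 16 of 30 pattern-triggered immunity genes (22 adjusted over the list alone), PROPEP2 at -3.23 ± 0.67 among them. Together they had camera adjusted p = 2e-12 and adjusted p = 0.091 with an estimated correlation. It was negative for 14 and positive for 1 of 21 camalexin and indole glucosinolate genes (17 and 1 adjusted over the list alone), CYP81F2 at -3.12 ± 0.43. All members together had camera adjusted p = 1.7e-11 and adjusted p = 0.1 with an estimated correlation. The interaction was positive for 19 of 34 photosynthesis genes (23 adjusted over the list alone), plastocyanin PETE1 at 2.38 ± 0.34, with camera adjusted p = 6.6e-12 and adjusted p = 0.31 with an estimated correlation. BAM5 (-6.02 ± 0.99), EXT13 (-5.09 ± 0.51), AGP30 (-4.99 ± 0.73), AOC1 (-3.81 ± 0.55), AOC2 (-3.45 ± 0.55), BIP3 (-4.56 ± 1.08) and PRP3 (-2.77 ± 0.46) were negative as well. edgeR called 2262 genes, 966 positive and 1296 negative, and 3721 with the replicate block set within each time, a setting chosen after the data were seen. The 10 h libraries stand in the other count table, so 10 h was not tested against 2 h or 24 h.

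**Figure D2:**
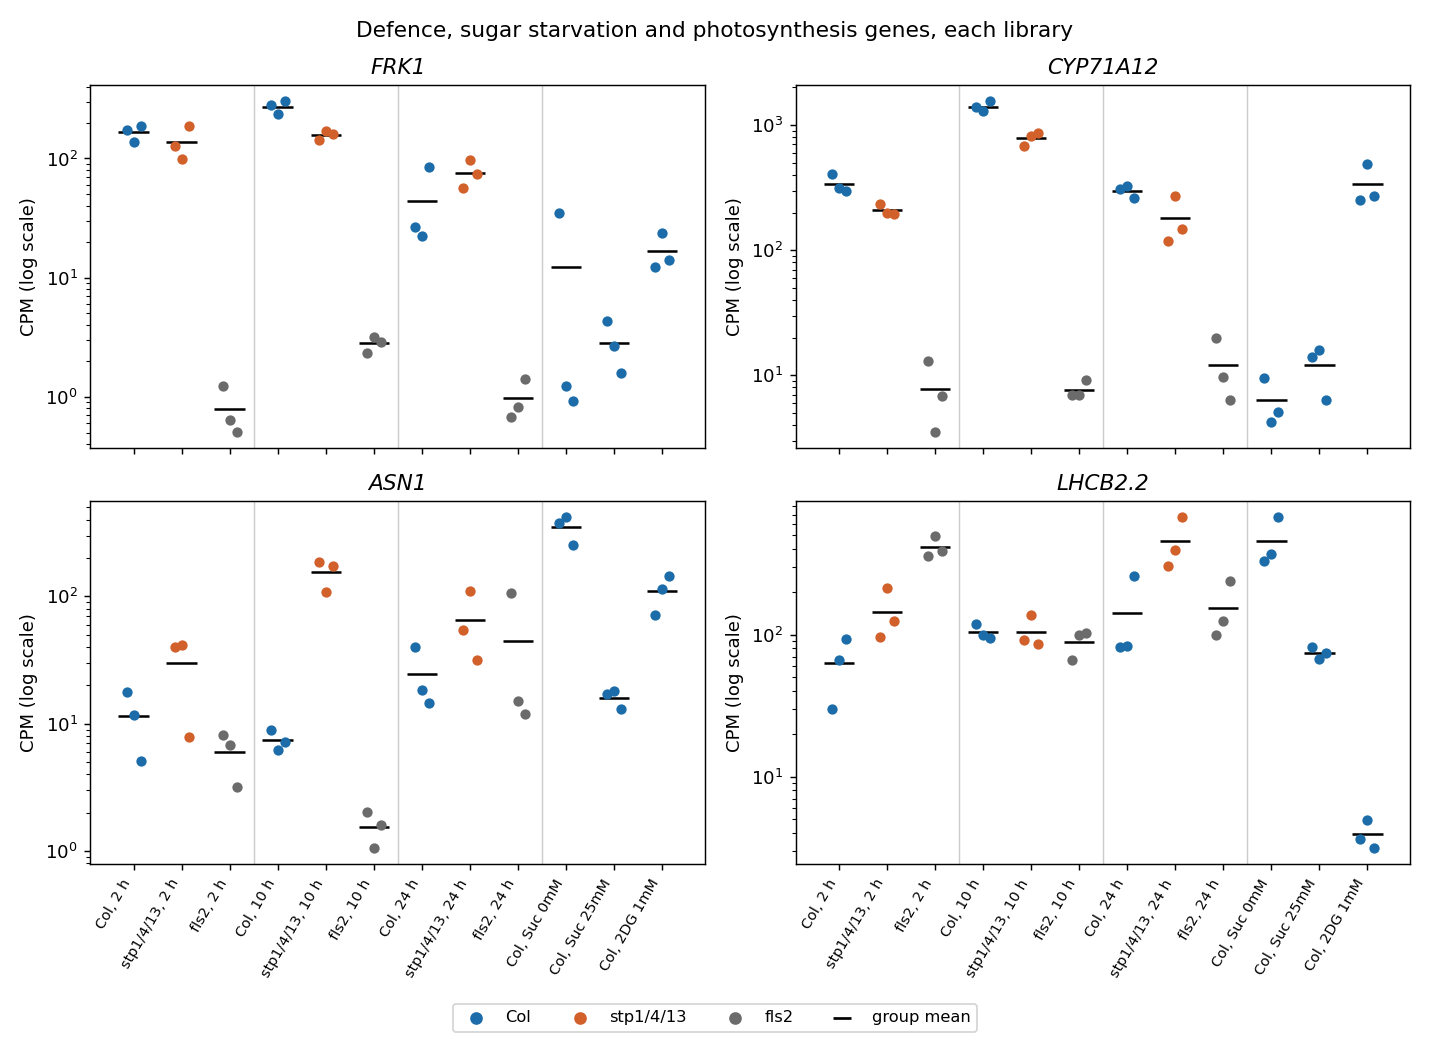
Normalised read counts (CPM, log axis) of FRK1, CYP71A12, ASN1 and LHCB2.2 in each library (points) of the 12 groups, with the group mean as a black line; CPM were scaled separately within the 2 h and 24 h, the 10 h, and the sucrose and 2DG libraries. CYP71A12 averaged 1410 CPM in Col and 7.67 CPM in fls2 at 10 h, and ASN1 155 CPM in stp1/4/13 and 7.47 CPM in Col at 10 h.

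The comparison of stp1/4/13 with Col asks how loss of the 3 sugar transporters alters the flg22-treated transcriptome. At 2 h, few genes differed in the main fit, which has no term for the trial. Besides STP13 (-4.53 ± 0.32), STP1 (-3.85 ± 0.70) and STP4 (-2.77 ± 0.25), the genes lower in stp1/4/13 included MRD1 (-4.30 ± 0.56) and NFXL2 (-3.18 ± 0.42). Those higher included GASA6 (2.28 ± 0.42), the plastid sigma factor SIG4 (2.14 ± 0.42), CCB3 (1.72 ± 0.33) and the chloroplast NDH complex subunits PnsB3 (1.65 ± 0.31) and PnsB2 (1.38 ± 0.25). FLS2 did not pass (-0.30 ± 0.27, edgeR adjusted p = 0.87). No member of the 17 lists passed over all genes tested. Photosynthesis genes lay higher as a group, with 31 of 34 past the threshold when adjusted over the list alone (camera adjusted p = 7.2e-25, adjusted p = 0.23 with an estimated correlation). The jasmonate list lay lower (0 of 30 adjusted over the list alone, camera adjusted p = 5e-10, adjusted p = 0.23 with an estimated correlation). So did the pattern-triggered immunity list (0 of 30 adjusted over the list alone, camera adjusted p = 5.9e-08, adjusted p = 0.23 with an estimated correlation). The sugar starvation list had camera adjusted p = 0.051 and, with the trial as a block, 0.034. edgeR called 47 of 21463 genes, 37 higher and 10 lower, and 1945 had an unadjusted p below 0.05. With the trial as a block 126 genes passed, and 489 with the block set within each time, chosen after the data were seen. DESeq2 called 227, and with only these 6 libraries in the fit 27 passed, 8 of them higher. The count was 11 without Col library 1, 18 without Col library 2, 12 without Col library 3 and 8 without stp1/4/13 library 2. GASA6, SIG4, CCB3, PnsB3, PnsB2 and STP1 lost their calls without at least 1 library. Over the alternatives, their adjusted p ranged from 2.3e-05 to 0.23 (GASA6), 1.9e-04 to 0.37 (SIG4), 2.8e-04 to 0.25 (CCB3), 2.4e-04 to 0.23 (PnsB3), 1.7e-04 to 0.24 (PnsB2) and 1.2e-04 to 0.12 (STP1). Of these 6 genes, CCB3 alone kept its call with only the 6 libraries in the fit.

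At 10 h, genes induced by sugar starvation were higher in stp1/4/13 than in Col. The asparagine synthetase ASN1 rose by 4.38 ± 0.23, from a mean of 7.47 to 155 CPM. The dark-inducible genes SEN1 and DIN2 rose by 3.70 ± 0.22 and 3.25 ± 0.26, the BTB-TAZ gene BT1 by 3.35 ± 0.28 and the aldolase FBA5 by 5.94 ± 0.80. The Calvin cycle kinase PRK (1.55 ± 0.23) and the Rubisco small subunit gene RBCS3B (1.38 ± 0.22) were higher too. The ER chaperone BIP3 (-1.91 ± 0.20) and the defence gene NHL10 (-1.59 ± 0.20) were lower. MRD1 (-5.14 ± 0.29), NFXL2 (-2.59 ± 0.25) and CYP79F1 (-2.32 ± 0.29), an enzyme of aliphatic glucosinolates, fell beside STP1 (-4.99 ± 0.30), STP13 (-4.40 ± 0.25) and STP4 (-2.09 ± 0.15). FLS2 did not pass (-0.24 ± 0.19, edgeR adjusted p = 0.48).

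In the sugar starvation list 23 of 29 members rose in stp1/4/13 at 10 h (25 adjusted over the list alone), with camera adjusted p = 5.4e-24 and adjusted p = 0.014 with an estimated correlation. Photosynthesis genes rose in 26 of 34 cases (30 adjusted over the list alone), with camera adjusted p = 5.4e-15 and adjusted p = 0.37 with an estimated correlation. ER protein folding genes fell in 11 of 18 cases (15 adjusted over the list alone), BIP2 by -0.96 ± 0.14 log2 units, with camera adjusted p = 1.1e-07 and adjusted p = 0.071 with an estimated correlation. Pattern-triggered immunity genes fell in 7 of 29 cases (9 adjusted over the list alone), WRKY40 by -1.04 ± 0.24 and WRKY53 by -0.98 ± 0.20. Over the whole list, the members had camera adjusted p = 1.9e-05 and adjusted p = 0.37 with an estimated correlation. Camalexin and indole glucosinolate genes fell in 8 of 21 cases (9 lower and 1 higher adjusted over the list alone), CYP71A13 by -1.77 ± 0.42 and the camalexin synthase PAD3 by -1.33 ± 0.36. The list had camera adjusted p = 6.8e-04 and adjusted p = 0.56 with an estimated correlation. In the salicylic acid list 5 of 29 fell (6 adjusted over the list alone), the transporter EDS5 by -1.07 ± 0.26, with camera adjusted p = 5.2e-04 and adjusted p = 0.41 with an estimated correlation. Heat shock genes fell in 4 of 10 cases (7 adjusted over the list alone), ROF2 by -1.58 ± 0.30, with camera adjusted p = 9.1e-04 and adjusted p = 0.4 with an estimated correlation. Sugar transport genes rose in 5 of 21 cases (6 adjusted over the list alone, camera adjusted p = 0.13), namely SWEET1 (1.75 ± 0.23), STP14 (1.54 ± 0.20), SWEET2 (1.43 ± 0.18) and 2 others. The dehydrin COR47 (0.76 ± 0.14), the nitrate reductase NIA1 (1.34 ± 0.14) and the ethylene synthesis gene ACS6 (-1.08 ± 0.23) also passed. Root tissue markers moved both ways, with PRP3 (2.23 ± 0.68) and CASP5 (1.97 ± 0.53) higher and COBL9, which had few counts, lower. edgeR called 2447 of 19561 genes, 1501 higher and 946 lower. The count was 1307 without Col library 1, 1366 without stp1/4/13 library 1 and 1416 without Col library 3. PAD3 lost its call with DESeq2 and without any 1 library but Col library 2 (adjusted p from 1.9e-05 to 0.085 over the alternatives). EDS5 lost its call without Col library 1 or stp1/4/13 library 1 (0.0024 to 0.11), and CYP71A13 without stp1/4/13 library 1 or 3 (9.9e-05 to 0.059).

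At 24 h, the defence genes GRX480, DLO1 and PAD3 were lower in stp1/4/13 than in Col. The glutaredoxin GRX480 fell by -3.01 ± 0.65 log2 units and the salicylic acid hydroxylase DLO1 by -2.95 ± 0.47. PAD3 fell from 58.8 ± 22.9 to 14.6 ± 3.31 CPM. Not all defence genes had lower means. FRK1 stood at 75.8 ± 20.1 CPM in stp1/4/13 and 44.3 ± 34.7 in Col, and PER4 at 54 ± 26.5 and 44.1 ± 6.67. ARD3, an enzyme of the methionine cycle (-5.09 ± 0.83), the glutathione transferase GSTU3 (-4.09 ± 0.74) and MRD1 (-5.69 ± 0.63) fell beside STP1 (-5.82 ± 0.77), STP13 (-3.56 ± 0.31) and STP4 (-1.93 ± 0.24). The xylosidase BXL1 rose by 2.38 ± 0.50 and the nicotianamine synthase NAS3 by 2.25 ± 0.31. FLS2 did not pass (-0.16 ± 0.27, edgeR adjusted p = 0.75).

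Photosynthesis genes rose in 22 of 34 cases in stp1/4/13 at 24 h (33 adjusted over the list alone), LHCB2.2 by 1.69 ± 0.48 and LHCB4.2 by 1.47 ± 0.41. As a list they had camera adjusted p = 5.3e-17 and adjusted p = 0.34 with an estimated correlation. Jasmonate genes fell in 9 of 30 cases (13 adjusted over the list alone), the repressor JAZ5 by -2.56 ± 0.59 and the jasmonate hydroxylase CYP94C1 by -2.43 ± 0.55. Together they had camera adjusted p = 4.1e-07 and adjusted p = 0.34 with an estimated correlation. Salicylic acid genes fell in 8 of 30 cases and rose in 1 (9 and 2 adjusted over the list alone), with camera adjusted p = 0.0049 and adjusted p = 0.34 with an estimated correlation. Camalexin and indole glucosinolate genes fell in 3 of 21 cases (8 lower and 2 higher adjusted over the list alone), GGP1 by -0.77 ± 0.18. All members together had camera adjusted p = 0.0069 and adjusted p = 0.5 with an estimated correlation. Pattern-triggered immunity genes fell in 4 of 30 cases (7 adjusted over the list alone), the NADPH oxidase RBOHD by -0.98 ± 0.29, with camera adjusted p = 0.041 and adjusted p = 0.53 with an estimated correlation. Cell cycle genes rose in 2 of 14 cases (3 adjusted over the list alone), with camera adjusted p = 9.5e-04 and adjusted p = 0.34 with an estimated correlation. BZIP60 (-0.92 ± 0.17), SWEET1 (1.19 ± 0.28) and ACS8 (1.79 ± 0.41) passed as well, and of the sugar starvation list 1 of 29 members rose (0 adjusted over the list alone, camera adjusted p = 0.59). edgeR called 1934 of 21463 genes, 958 higher and 976 lower. Settings chosen after the data were seen gave 4489 (block within each time) and 3066 (without the 3 libraries numbered 3 at 24 h). The blocked fit called 3227, DESeq2 2971, and the fit of these 6 libraries alone 184, in which BZIP60, LHCB2.2, LHCB4.2, JAZ5, CYP94C1, RBOHD, GGP1, ACS8 and SWEET1 did not pass. The count was 450 without Col library 1, 524 without Col library 2, 3740 without Col library 3, 508 without stp1/4/13 library 2 and 753 without stp1/4/13 library 3. Of the genes named here, LHCB2.2, LHCB4.2, JAZ5, RBOHD and SWEET1 lost their calls without any of these libraries but Col library 3. CYP94C1 lost its call without Col library 2 or stp1/4/13 library 2 or 3, GGP1 and ACS8 without Col library 2 or stp1/4/13 library 2, and GRX480 without Col library 1 or stp1/4/13 library 2.

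The interaction of stp1/4/13 against Col between 2 h and 24 h passed for 6 genes, 4 positive and 2 negative (edgeR), 1469 having an unadjusted p below 0.05. Those that met the rule for named genes were the cytochrome P450 gene CYP71B26 (positive, edgeR adjusted p = 0.044) and the mitochondrial alternative oxidase AOX1A (-1.59 ± 0.27, edgeR adjusted p = 0.044). Of the other 4, M17 and MYBL2, which lay below the level that the rule asks for and were looked up after the result was seen, have a symbol. No list member passed. The cell cycle list lay higher (0 of 14 adjusted over the list alone) and the heat shock list lower (0 of 11 adjusted over the list alone), each with camera adjusted p = 0.031 and adjusted p = 0.81 with an estimated correlation. With the trial as a block the photosynthesis list had camera adjusted p = 0.031 in place of 0.064, and the abscisic acid list 0.034 in place of 0.061. A block within each time gave 90 genes and the fit without the 3 libraries numbered 3 at 24 h gave 123, both settings chosen after the data were seen. The blocked fit called 16 genes and DESeq2 48, while RLE scaling left 3 and the 12 libraries alone 2. The count was 25 without Col library 3 of 24 h, and 2 without Col library 1 or stp1/4/13 library 2 of 2 h. It was 1 without stp1/4/13 library 1, Col library 2 or Col library 3 of 2 h or without Col library 1, Col library 2, stp1/4/13 library 2 or stp1/4/13 library 3 of 24 h. CYP71B26 and AOX1A lost their calls with RLE scaling, in the fit of the 12 libraries and without any 1 library but Col library 3 of 24 h. CYP71B26 also lost its call with no filter on low counts (edgeR adjusted p from 8.4e-05 to 0.25 for CYP71B26 and from 4.9e-05 to 0.25 for AOX1A over the alternatives).

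Set against fls2, stp1/4/13 had higher levels of defence genes after flg22. Without an untreated stp1/4/13 group, a response to flg22 cannot be told apart here from effects of the stp1/4/13 genotype itself. FRK1 stood 7.43 ± 0.55 above fls2 at 2 h and 6.27 ± 0.53 at 24 h, PROPEP3 6.64 ± 0.53 at 2 h and PER4 7.18 ± 0.28 at 10 h. CYP71A12 stood higher by 4.74 ± 0.46 at 2 h, 6.68 ± 0.18 at 10 h and 3.91 ± 0.44 at 24 h. ASN1 stood 6.62 ± 0.28 above fls2 at 10 h and CYP82C2 7.20 ± 0.67 at 24 h. Pattern-triggered immunity genes rose in 27 of 30 cases at 2 h (28 adjusted over the list alone, camera adjusted p = 4.1e-21, adjusted p = 0.014 with an estimated correlation). They rose in 24 of 29 at 10 h (24 adjusted over the list alone, camera adjusted p = 3.7e-10, adjusted p = 0.14 with an estimated correlation). At 24 h, 16 of 30 rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 4.2e-09, adjusted p = 0.14 with an estimated correlation). Root tissue markers rose in 2 and fell in 1 of 18 cases at 2 h (3 and 3 adjusted over the list alone, camera adjusted p = 0.96, adjusted p = 0.97 with an estimated correlation). At 10 h, 4 of 17 rose and 7 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.29, adjusted p = 0.68 with an estimated correlation). At 24 h, 8 of 18 fell (8 adjusted over the list alone, camera adjusted p = 5.9e-05, adjusted p = 0.14 with an estimated correlation). The sugar starvation list rose in 28 of 29 cases at 10 h (28 adjusted over the list alone, camera adjusted p = 2e-14, adjusted p = 0.052 with an estimated correlation). At 10 h, blocking by trial moved the photosynthesis list from camera adjusted p = 0.063 to 0.042 and the sugar transport list from 0.046 to 0.051. edgeR called 5489 genes at 2 h, 10215 at 10 h and 4264 at 24 h. Col and stp1/4/13 shared 3145 genes higher than fls2 at 2 h, 4164 at 10 h and 1436 at 24 h, where independent lists would share 634, 1310 and 270. The correlation across genes was 0.91, 0.90 and 0.72 with covariances of 1.89 at 10 h and 0.68 at 24 h. Unchanged groups simulated against the same fls2 libraries gave 0.49, 0.50 and 0.49 with covariances of 0.08 at 2 h, 0.06 at 10 h and 0.08 at 24 h. They gave no shared calls, but unchanged groups give few calls at all. This therefore does not measure how many shared genes the common controls add. Part of the excess may come from the shared controls.

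The size of the response in stp1/4/13 was compared with that in Col over the genes higher in Col than in fls2. Response here means the difference from fls2, which includes effects of the genotypes themselves. The median ratio of the log2 responses was 0.862 at 2 h over 4024 genes, 0.940 at 10 h over 4863 genes and 0.796 at 24 h over 2355 genes. Stp1/4/13 libraries simulated as equal to Col gave 0.970 (0.961 to 0.979 in 20 draws), 0.982 (0.977 to 0.986) and 0.946 (0.937 to 0.956), since the genes were chosen on the Col libraries. Of these genes 83.8%, 58.6% and 68.1% were lower in stp1/4/13 than in Col, against a mean of 57.1%, 55.0% and 60.3% in the simulated libraries (at most 59.4%, 56.4% and 61.7%). Computed from libraries with the same number, the ratio was 0.889, 0.820 and 0.870 at 2 h, 0.903, 0.978 and 0.953 at 10 h and 0.708, 0.826 and 0.849 at 24 h (mean 0.860 ± 0.036, 0.945 ± 0.038 and 0.794 ± 0.076 SD, n = 3). The simulated draws varied less than these sets, with an SD of 0.0046 at 2 h, 0.0027 at 10 h and 0.0055 at 24 h. Their ranges may therefore be too narrow. At 10 h the set at 0.978 lay within the simulated range, so the draws do not settle whether that ratio is reduced. At 24 h the ratio was 0.632 without Col library 3.

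The Col libraries titled 2DG_1mM were compared with those titled Suc_0mM, which asks what the glucose analogue changes without sucrose. Titles and the treatment label name 2DG_1mM and Suc_25mM the other way round for 6 libraries, and the groups here follow the titles. Heme oxygenase HO4 rose by 10.20 ± 0.43, from 0.253 ± 0.0982 to 307 ± 55.7 CPM, and the jasmonate marker TAT3 by 9.13 ± 0.82. Against a group at 0 in all 3 libraries titled Suc_0mM, with a floor of 3 counts over the group, the phosphate starvation gene SPX3 was at least 603-fold higher, CPK22 at least 352-fold, PP2-B2 at least 310-fold, and the systemic resistance enzyme FMO1 at least 164-fold. The antenna gene LHCB2.2 fell from 458 ± 187 to 3.92 ± 0.906 CPM (-6.86 ± 0.36). In the libraries titled 2DG_1mM, UMAMIT13, RL4 and AMP1 had no count and were at least 207-fold, 149-fold and 137-fold lower. STP13 rose by 3.47 ± 0.38, while STP1 (-2.43 ± 0.34), STP4 (-1.94 ± 0.22) and FLS2 (-3.60 ± 0.55) fell.

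In the libraries titled 2DG_1mM, 26 of 29 salicylic acid genes were higher than in those titled Suc_0mM (27 higher and 1 lower adjusted over the list alone), with WRKY38 at least 152-fold and the glucanase PR2 at least 87.9-fold higher. Over the whole list, the members had camera adjusted p = 8e-14 and adjusted p = 0.13 with an estimated correlation. Jasmonate genes rose in 21 of 29 cases (22 adjusted over the list alone), JAZ8 by 6.10 ± 0.93 and CYP94B3 by 5.57 ± 0.45. The list had camera adjusted p = 5.1e-08 and adjusted p = 0.25 with an estimated correlation. Camalexin and indole glucosinolate genes rose in 12 of 20 cases (12 adjusted over the list alone), CYP71A12 by 5.74 ± 0.48 and PAD3 by 4.89 ± 0.86. As a list they had camera adjusted p = 2e-05 and adjusted p = 0.37 with an estimated correlation. Pattern-triggered immunity genes rose in 13 and fell in 3 of 30 cases (13 and 3 adjusted over the list alone), with NHL10 at 5.32 ± 0.42, MPK11 at 4.98 ± 0.92 and WRKY53 at -5.14 ± 1.14. Together they had camera adjusted p = 5.4e-04 and adjusted p = 0.43 with an estimated correlation. All 34 photosynthesis genes fell (34 adjusted over the list alone), RBCS1B by -6.32 ± 0.42 and LHCB1.1 by -5.56 ± 0.34, with camera adjusted p = 7.1e-13 and adjusted p = 0.25 with an estimated correlation. ER protein folding genes rose in 14 and fell in 2 of 18 cases (14 and 2 adjusted over the list alone), BIP3 by 5.64 ± 0.93. All members together had camera adjusted p = 2e-05 and adjusted p = 0.25 with an estimated correlation. Abscisic acid genes rose in 11 of 16 cases (12 adjusted over the list alone), the phosphatase HAI1 by 4.69 ± 0.61, with camera adjusted p = 1.2e-04 and adjusted p = 0.25 with an estimated correlation.

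Calcium-dependent kinases rose in 5 of 10 cases in the libraries titled 2DG_1mM (6 adjusted over the list alone), CPK29 by 3.91 ± 0.29. Over the whole list, the members had camera adjusted p = 0.0034 and adjusted p = 0.25 with an estimated correlation. Root tissue markers fell in 11 of 17 cases (11 adjusted over the list alone), HKT1 at least 41.8-fold and EXPA7 at least 36.5-fold. The members as a group had camera adjusted p = 0.0041 and adjusted p = 0.25 with an estimated correlation. Cell cycle genes fell in 6 of 12 cases (6 adjusted over the list alone), with camera adjusted p = 0.024 and adjusted p = 0.25 with an estimated correlation. Guard cell markers fell in 3 of 7 cases (3 adjusted over the list alone, camera adjusted p = 0.18). The sugar starvation list split, 7 higher and 8 lower of 29 (8 and 9 adjusted over the list alone, camera adjusted p = 0.38), with DIN11 at 5.08 ± 0.60, DIN2 at 3.66 ± 0.46 and the mannose-6-phosphate isomerase DIN9 at 2.69 ± 0.44. Ethylene genes split, 4 higher and 4 lower of 17 (4 and 4 adjusted over the list alone, camera adjusted p = 0.38), with ERF6 at 4.62 ± 0.53 and ACS2 at 4.46 ± 0.44. The sugar-induced metabolism list had 4 higher and 3 lower of 17 (4 and 3 adjusted over the list alone, camera adjusted p = 0.47, adjusted p = 0.72 with an estimated correlation), with GPT2 at 6.21 ± 0.74. The sugar transport list had 5 higher and 6 lower of 21 (5 and 6 adjusted over the list alone, camera adjusted p = 0.92, adjusted p = 0.92 with an estimated correlation), with SWEET1 at -6.68 ± 0.70 and SWEET11 at -4.78 ± 0.66. Within the group titled Suc_0mM, FRK1 stood at 34.8 CPM in library 1 and at 1.23 and 0.926 in libraries 2 and 3, and 9119 genes were called without library 1. edgeR called 9697 of 19727 genes, 4203 higher and 5494 lower, with a median log2 change of -0.21 over all genes tested. With the groups taken from the treatment label the same comparison called 2463.

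The libraries titled Suc_25mM were compared with those titled Suc_0mM. The sugar starvation gene ASN1 fell by -4.45 ± 0.33 log2 units, from 351 ± 86.3 to 16.0 ± 2.66 CPM, and BCAT-2 by -3.33 ± 0.39. The glucose-6-phosphate translocator GPT2 rose by 6.97 ± 0.76 and G6PD3, a plastid glucose-6-phosphate dehydrogenase, by 4.00 ± 0.51. SPX3 was at least 156-fold higher, and the lipid synthase MGDC (6.91 ± 0.64), another phosphate starvation gene, rose as well. The late embryogenesis gene M17 (-9.33 ± 0.36), the lipase MPL1 (-5.55 ± 0.41), HOL2 (-5.48 ± 0.40) and BXL1 (-4.64 ± 0.51) fell. STP1 (-3.37 ± 0.35) and STP4 (-2.06 ± 0.22) were lower with sucrose. STP13 differed by 1.06 ± 0.35 and did not pass (edgeR adjusted p = 0.075, 0.016 with the trial as a block, and 2.8e-05 to 0.24 over the alternatives), nor did FLS2 (-0.20 ± 0.48, edgeR adjusted p = 0.85).

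With the titled 25 mM sucrose, 21 of 29 sugar starvation genes fell and 1 rose (21 and 2 adjusted over the list alone), DIN9 by -3.40 ± 0.53 log2 units. The members as a group had camera adjusted p = 8.2e-14 and adjusted p = 0.17 with an estimated correlation. Photosynthesis genes fell in 27 of 34 cases (32 adjusted over the list alone), LHCB1.4 by -3.76 ± 0.31, LHCB2.2 by -2.62 ± 0.29 and LHCB2.1 by -2.58 ± 0.38. The members as a group had camera adjusted p = 8.6e-20 and adjusted p = 0.24 with an estimated correlation. Camalexin and indole glucosinolate genes rose in 9 of 20 cases and fell in 1 (11 and 1 adjusted over the list alone), PAD3 by 4.76 ± 0.85, TSA1 by 2.27 ± 0.41 and GGP1 by 1.83 ± 0.32. The members as a group had camera adjusted p = 2.2e-04 and adjusted p = 0.59 with an estimated correlation. Jasmonate genes rose in 8 of 29 cases and fell in 1 (9 and 1 adjusted over the list alone), CORI3 by 5.20 ± 0.64, the chitinase CHIB by 2.77 ± 0.23 and AOC3 by 2.64 ± 0.45. The members as a group had camera adjusted p = 0.002 and adjusted p = 0.59 with an estimated correlation. Salicylic acid genes rose in 7 of 29 cases (7 adjusted over the list alone), with camera adjusted p = 0.0076 and adjusted p = 0.59 with an estimated correlation. Of the list of sugar-induced metabolism 5 of 17 rose (6 adjusted over the list alone, camera adjusted p = 0.18). The transporter genes SWEET2 (-2.20 ± 0.20) and SUC2 (-1.73 ± 0.25), the phloem sucrose loader, were lower. edgeR called 2463 of 19727 genes, 1264 higher and 1199 lower, and 9697 with the groups taken from the treatment label. The count was 1277 without the library titled Suc_25mM 1 and 1507 without Suc_25mM 3.

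Between the libraries titled 2DG_1mM and Suc_25mM, CYP71A12 was higher in 2DG_1mM by 4.80 ± 0.46 and DIN9 by 6.09 ± 0.55, and LHCB2.2 lower by a log2 difference of -4.24 ± 0.33. Sugar starvation genes were higher in 23 and lower in 2 of 29 cases (23 and 2 adjusted over the list alone), with camera adjusted p = 7.6e-08 and adjusted p = 0.2 with an estimated correlation. Salicylic acid genes were higher in 26 and lower in 1 of 29 cases (26 and 1 adjusted over the list alone), with camera adjusted p = 4.3e-12 and adjusted p = 0.1 with an estimated correlation. edgeR called 9731 genes, 4213 higher and 5518 lower in 2DG_1mM, with a median log2 change of -0.23 over all genes tested. The changes against Suc_0mM in the 2DG_1mM and Suc_25mM libraries, as titled, shared 690 higher genes where independent lists would share 269, and 646 lower genes where they would share 334, while 416 genes moved in opposite directions. The correlation across genes, which are not independent replicates, was 0.31 with a covariance of 0.88. Unchanged groups simulated against the same 3 libraries gave 0.50 with a covariance of 0.17. They gave no shared calls, but unchanged groups give few calls at all, so this does not measure what the common controls add. Part of the excess may come from the shared controls.

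**Figure D3:**
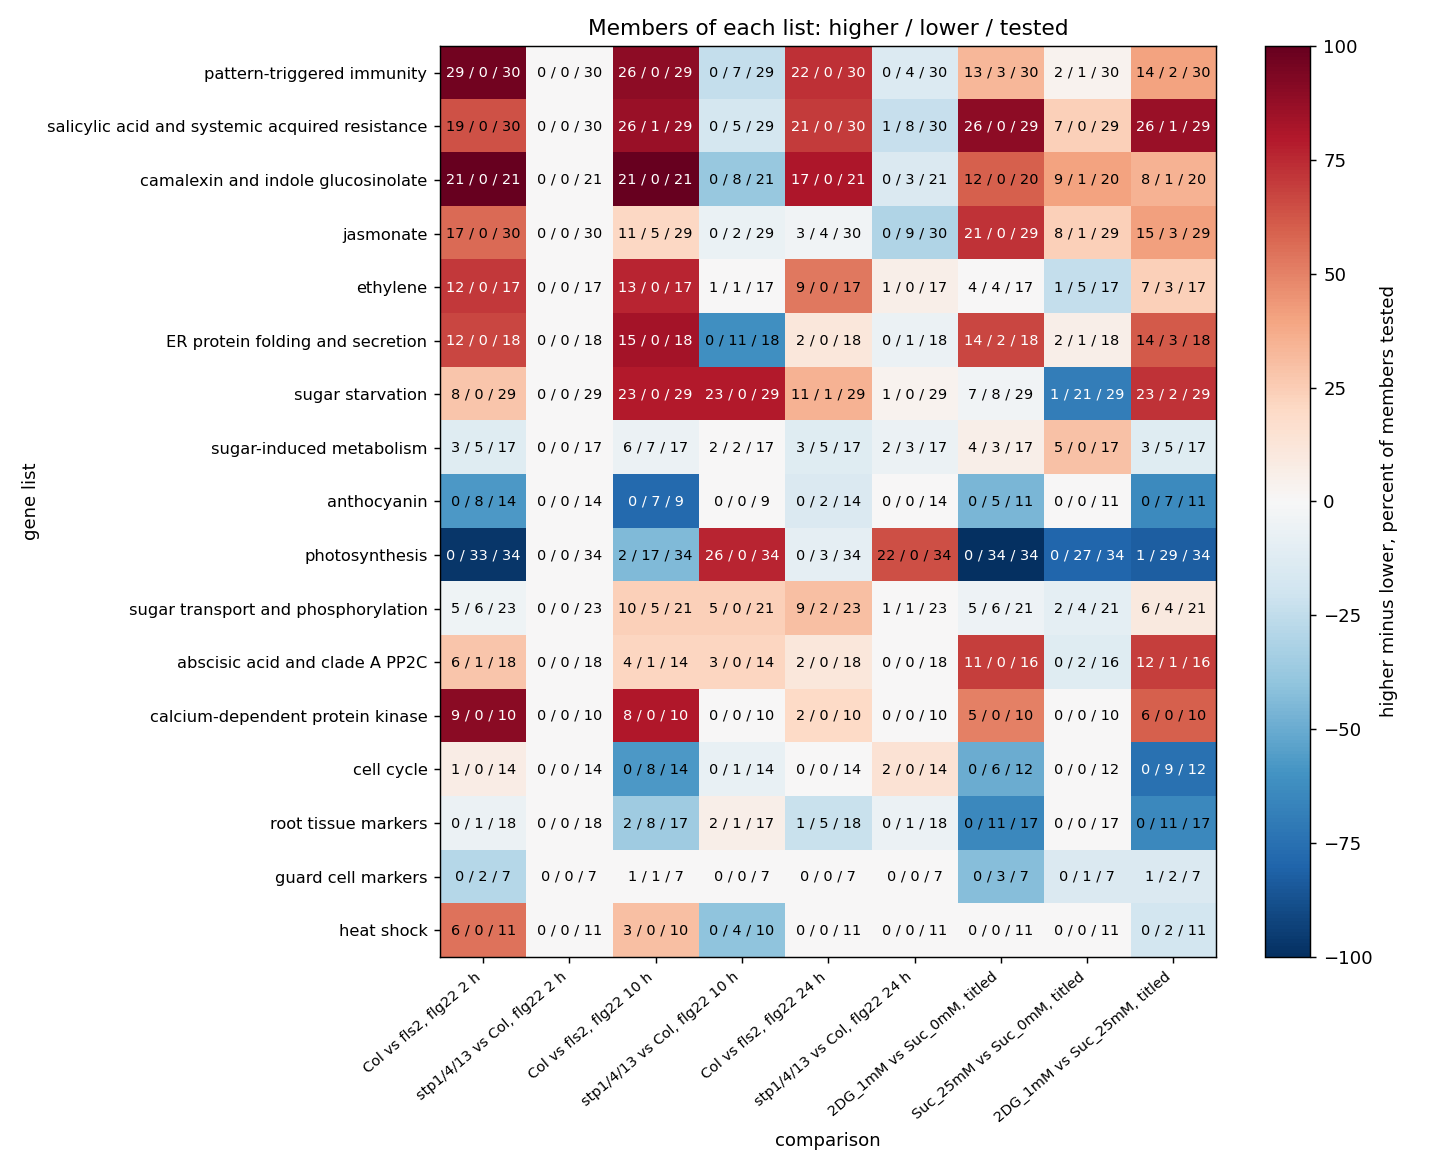
Each cell gives the members of a fixed gene list (vertical axis) that were higher, lower and tested in a comparison (horizontal axis) at adjusted p below 0.05 over all genes, and its colour the difference of higher and lower as a percent of members tested. The sugar starvation list had 23 of 29 members higher in stp1/4/13 than Col at 10 h and 21 of 29 lower with the titled 25 mM sucrose.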

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

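Of the tests in this part, the tests for mixing with Col or fls2 RNA in a stp1/4/13 library, and the ratio without that library, were chosen only after the result was seen.

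The difference between Col and fls2 changed between 2 h and 24 h in 2262 genes, and that between stp1/4/13 and Col in 6, each by a test of the interaction in edgeR. The libraries were put into 30 groupings, the real one included, with the times shuffled within each genotype. Only the real one gave as many genes for Col and fls2 (2015, and 1433 in the highest other). For stp1/4/13 and Col 2 groupings did, the real one among them (2 genes, and 1356 in the highest other). Shuffling the times also carries the difference between 2 h and 24 h into the interaction, so these splits of the libraries decide nothing about chance. For Col and fls2, edgeR gave an unadjusted p below 0.05 in 5128 of 21463 genes, besides the 2262 past the adjusted threshold. The count of unadjusted p-values comes from the same fit, which leaves out the trial, and genes are not independent. It therefore adds no separate support to the 2262 calls, which argue against chance only within that model. For the 6 genes of stp1/4/13 and Col, with 1469 at an unadjusted p below 0.05, chance stays open.

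For each comparison of 3 with 3 libraries, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. With these 6 libraries in the fit, the real count and the highest of the others were 7936 and 0 for Col against fls2 at 2 h, 9919 and 0 at 10 h, and 2090 and 0 at 24 h. For stp1/4/13 against Col they were 27 and 1, 3404 and 0, and 184 and 0, and for stp1/4/13 against fls2 6110 and 0, 9714 and 0, and 3127 and 0. As titled, they were 8026 and 0 for 2DG_1mM against Suc_0mM, 3221 and 0 for Suc_25mM against Suc_0mM, and 9276 and 0 for 2DG_1mM against Suc_25mM.

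Titles and treatment labels name 2DG_1mM and Suc_25mM the other way round for 6 libraries. If the titles were swapped, libraries titled 2DG_1mM would lie closer to plants kept in sucrose medium than those titled Suc_25mM. In 9 of 9 library pairs, a library titled Suc_25mM correlated more with an fls2 library of 10 h, kept in 25 mM sucrose, than any titled 2DG_1mM did (r of 0.878 to 0.897 against 0.545 to 0.594, and 0.808 to 0.839 for Suc_0mM). This argues against mislabelled titles for all 3 pairs of libraries, and how the treatment labels arose stays open.

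STP1 stood at 29.1 CPM in stp1/4/13 library 2 at 2 h and at a mean of 2.96 CPM in the other 2 libraries. Mixing with Col RNA would need 36.1 CPM of STP13, and 7.68 CPM was found against a mean of 7.93 in the others, which argues against it. Mixing with fls2 RNA would need 22.4 CPM of MRD1, and 9.04 CPM was found, which argues against it as the whole cause, although MRD1 lay above both other libraries (0.236 and 5.24 CPM) and FLS2 below them (25.8 CPM against 42.2 and 46.3). FLS2 was also lowest in Col library 2 at 2 h (34.3 CPM, against 55.5 in library 1 and 51.5 in library 3), so its low value is not particular to the stp1/4/13 library. What raised STP1 stays open, and no biological explanation was tested. Without this library the median ratio of the stp1/4/13 to the Col response at 2 h was 0.885 in place of 0.862.

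Between stp1/4/13 and Col, 27 genes changed in the same direction at 2, 10 and 24 h, 19 higher and 8 lower, where independent lists would share 0.16. STP1, STP4 and STP13 were among the lower ones, with MRD1, its neighbour HEI10, NFXL2 and GMI1, while SIG4, PnsB2 and PnsB3 were among the higher. The largest rise was in AT1G64795 (log2 5.89 at 2 h, 8.56 at 10 h and 6.97 at 24 h), which was not tested in the sucrose comparison. The largest fall was in AT3G01345 (-5.33, -5.24 and -6.38). With sucrose, AT3G01345 differed by -0.52 and MRD1 by -0.06, and neither passed. A strain variant closely linked to the mutated loci would place the genes near these. Of the other 24, 0% lay within 200 loci of one, against 4.04% of all tested genes. This argues against a variant within that window as the main cause, and linkage over a longer segment was not tested. Lower sugar uptake would move the genes opposite to added sucrose. Of the 23 tested there, 34.8% did so past the threshold, namely 8 of the higher genes and 0 of the 5 lower ones. Among the higher genes tested, only PnsB3 lacked a negative log2 difference with sucrose (0.09). Among the 5 lower ones, only GMI1 had a positive difference (2.15, edgeR adjusted p = 0.14). The sucrose comparison recovered 3% of simulated 2-fold changes, with 200 genes and the photosynthesis list changed. The real comparison called 2463 genes, and the adjusted threshold depends on how many genes change. The 3% therefore does not measure how many of these genes were missed. Genes can be missed, and lower sugar uptake stays open. A variant elsewhere in the genome was not tested.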

How the results depend on the processing

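The block within each time, the removal of the 3 libraries numbered 3 at 24 h and the ratio without each library were chosen after seeing the data. Of 3563 values of 266 gene results chosen for the text under the alternatives, 3410 kept their side of the threshold without a reversal. Values without an adjusted p were left out. A change of direction was counted as a reversal only where either value passed the threshold. By this count 10 values reversed, each with the groups from the treatment label. The strict filter and the setting without a filter kept all 14 counts within 1.5 times the reported ones, RLE scaling 13, the replicate block and DESeq2 11 each, and the compared groups alone 10.

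With the groups from the treatment label, 2DG_1mM against Suc_0mM gave 2463 genes and Suc_25mM against Suc_0mM 9697. Because the groups exchange names, the log2 fold changes were BIP3 -3.25, DIN2 -1.89 and DIN9 -3.40 for the former, MPL1 2.05, HOL2 1.90, DIN9 2.69 and G6PD3 -0.92 for the latter, and CYP71A12 -4.80, LHCB2.2 4.24 and DIN9 -6.09 for 2DG_1mM against Suc_25mM. The replicate block, which pairs the libraries with the same number, gave 126 genes for stp1/4/13 against Col at 2 h, 3227 at 24 h and 16 for their interaction. The block within each time gave 489, 4489 and 90, and 3721 for the interaction of Col and fls2. DESeq2 gave 227, 2971 and 48, and RLE scaling 3 for the stp1/4/13 interaction. The compared groups alone, with fewer libraries to estimate the spread, gave 27 and 184 for stp1/4/13 against Col at 2 h and 24 h, 2090 for Col against fls2 at 24 h and 2 for the stp1/4/13 interaction. Without the 3 libraries numbered 3 at 24 h, stp1/4/13 against Col gave 3066 and its interaction 123. Apart from the exchange of groups, the cause was not tested.

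Leaving out each library gave 8 to 56 genes for stp1/4/13 against Col at 2 h, 1307 to 1708 at 10 h, 450 to 3740 at 24 h, 1 to 25 for their interaction and 1277 to 2214 for Suc_25mM against Suc_0mM. Of the 238 list results 125 passed with the preset correlation, 10 with an estimated correlation, 128 with the block, 126 with RLE scaling and 123 with fry. The ratio of the stp1/4/13 to the Col response was 0.900 at 10 h over genes called at 2 h, 0.689 and 0.719 at 24 h over genes called at 2 h and 10 h, and 0.632 to 0.861 at 24 h with each library left out. The cause of these shifts was not tested. In the simulated counts, 29% to 48% of 2-fold and 83% to 91% of 4-fold changes between stp1/4/13 and Col were recovered. Recovery did not rise with depth between 10 h and 2 h. It was 48% and 91% at 10 h (9.46 to 11.3 M counts per library). At 2 h (17.2 to 19.6 M) it was 29% and 84%. The adjusted threshold depends on how many genes change, so recovery in the real comparisons can differ.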

Other observations

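The overlaps between comparisons in this part were chosen after the comparisons had been seen, while the tests of the sucrose hypothesis were written before their results.

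The responses to flg22 overlapped between times, whose libraries are not shared. Of the genes changed between Col and fls2, 2901 were higher and 2214 lower at both 2 h and 10 h, where independent lists would share 966 and 888. At 2 h and 24 h these were 1704 and 732 (442 and 262 for independent lists), and at 10 h and 24 h 2084 and 1291 (572 and 405). Between stp1/4/13 and Col, 425 genes were higher and 154 lower at both 10 h and 24 h (72 and 45 for independent lists). Genes that differed between Col and fls2 at 24 h also changed with 2DG as titled, 1202 being higher in both and 981 lower in both (472 and 434 for independent lists). Genes are not independent replicates, so these values carry no test.

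A hypothesis is that genes altered in stp1/4/13 are sugar-responsive genes, through lower sugar uptake. At 10 h, 602 genes were higher in stp1/4/13 than in Col and lower in Suc_25mM than in Suc_0mM, as titled, which is 6.42 times the 94 that independent lists would share. The other way round there were 280 (60 for independent lists). At 24 h, 390 genes were lower in stp1/4/13 and higher with sucrose, 6.4 times the 61 for independent lists, and 318 the other way round (58 for independent lists). Both values exceed the 2-fold excess set beforehand, but the test does not separate lower sugar uptake from other causes. Between Col and fls2, which both carry the 3 transporter genes, 602 genes were higher in Col and lower with sucrose at 10 h and 566 the other way round (298 and 324 for independent lists), and at 24 h 357 and 333 (138 and 100). In the same direction as sucrose, stp1/4/13 against Col shared 18 higher and 5 lower genes at 10 h (96 and 58 for independent lists). At 24 h these were 2 and 3 (61 and 58). Col against fls2 shared 321 and 190 at 10 h (305 and 317), and 142 and 38 at 24 h (145 and 95). The fold changes correlated with those of sucrose at -0.20 and -0.21 for Col against fls2, and at -0.44 and -0.47 for stp1/4/13 against Col. The sugar starvation list had 23 of 29 members higher in stp1/4/13 at 10 h (camera adjusted p = 5.4e-24, adjusted p = 0.014 with an estimated correlation), but 1 of 29 at 24 h (camera adjusted p = 0.59, adjusted p = 0.95 with an estimated correlation). Whether the overlap comes from lower sugar uptake stays open. With 2DG as titled in place of sucrose, 936 genes were higher in stp1/4/13 and lower with 2DG at 10 h and 361 the other way round (425 and 191 for independent lists), and at 24 h 767 and 680 (264 and 198). Both comparisons use the same Suc_0mM libraries, so these overlaps are not separate from those with sucrose, and whether the overlap is specific to sucrose stays open.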
